A study of Mus musculus with 10 samples.

How the data were processed

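Poly(A)-selected RNA was sequenced from sorted splenic B cells of female C57BL/6J mice. Total RNA of 50000 cells per sample was taken up with a Zymo microprep kit and made into libraries with a KAPA stranded mRNA kit and polyA beads, per the labels' protocols. Groups were taken from the labelled cell type and LSD1 status: 2 knockout and 3 wild-type marginal zone B cell (MZB) libraries, and 3 knockout and 2 wild-type follicular B cell (FoB) libraries. No sample was left out and 0 columns of the deposited table stayed unassigned.

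The deposited table holds 1 signal value per gene and library, as mRNA per cell, which is its unit as named by the authors in the deposited table. STAR and the mm10 build were named, per the submitters' processing notes, with no version. The counter, the gene annotation, the gene filter and the way the factor from reads to molecules per cell was made are not given in the sources used here. The table lists 9690 genes by Entrez identifier, of which 9681 were matched to symbols and positions in the GRCm38.p6 annotation, the assembly of mm10, and 9 were not. Immunoglobulin and T cell receptor segment genes number 0 in the table, and 9578 genes lie above 0 in all libraries. A value of 0 occurs for 112 genes in at least 1 library.

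The values of a gene in the 10 libraries were whole multiples of what 1 read is worth, so that whole reads could be recovered for 100% of genes, with a largest deviation of 2.9e-05 against a tolerance of 0.1 reads. Tested on simulated data, the recovery gave reads for 100% of genes, and 99.86% of those equalled the simulated reads. The step depends on the gene, so that the values act as reads scaled per gene and per library. The recovered reads sum to 4161051 to 6711847 per library, with a median of 184 to 319 reads per gene, and the depth behind low genes is given as mean reads. No library equalled another (0 identical pairs). Within groups, Pearson correlations of log values across genes ran from 0.984 to 0.990, and the chi-square per gene between libraries ran from 1.91 to 7.34, so that replicates differed by more than counting error. Replicates of FoB knockout libraries 2 and 3 differed most.

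Differences were tested with limma 3.58.1 in R 4.3.3 on log2(value + 0.3), with lmFit, contrasts and eBayes with an intensity trend, over all 10 libraries with 1 coefficient per group and no covariate, two-sided. The pseudocount is the median positive value divided by 10, rounded. A fold change is therefore on the log2(value + 0.3) scale and understates the change of low genes. Genes needed a value of at least 0.3 in at least 2 libraries, which removed 0 genes. P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. The prior degrees of freedom, which weigh the spread pooled over genes, were 86.9 per cell and 5.2 after rescaling. Errors shared by all genes of a library count as if separate for each gene, so per-cell p-values can be too small. Rescaled values divide each library by a trimmed mean of log-ratios to the mean library (trims of 0.3 on the ratio and 0.05 on the level), with factors from 0.66 for FoB knockout library 3 to 1.67 for MZB knockout library 2. Lists were tested with limma camera at a preset correlation of 0.01, with an estimated correlation beside it, and lists with fewer than 3 tested genes had no such test. The table allowed this test for 20 of 28 lists. Total mRNA was compared by exact permutation, and overlaps by Fisher's exact test. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.

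The tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined, except where stated. The rule names Kdm1a first, then in each direction the 8 genes (4 for the difference between knockout effects) with the largest log2 change among those that passed, with no overlap between the compared libraries and a mean of at least 3 molecules per cell in the higher group. No absence of overlap was asked for the difference between effects. Receptor segments, predicted genes, clones, microRNA genes and symbols starting with LOC were left out of that rule, and up to 4 genes with the smallest p were added from each list. Only 7 genes that rose and 4 that fell met the rule in FoB. The alternatives were other pseudocounts, floors and scales, fits on the compared groups alone, without the trend, with library weights or with the replicate number as a block, a fold threshold, and leaving out each library in turn. limma voom on the recovered reads, rescaled values without 1 library, leaving out small RNA genes, and leaving the genes of the sort markers out of the lists were added after the data had been seen. Count models planned for whole reads were not run, and limma voom was run on the recovered reads instead.

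The tests were tried on simulated data with 200 changed genes among 9690. At 2-fold, 97% of changed genes were recovered per cell and 95% after rescaling for the MZB knockout comparison, 94% and 94% for FoB, and 99% and 97% for the cell types. At 4-fold these were 99% and 99%, 99% and 99%, and 100% and 99%. Unchanged genes called numbered 40 and 15, 11 and 7, and 6 and 1, each in 1 simulated data set. In 100 other simulations with an unchanged MZB knockout, per-cell calls had a median of 18 and a maximum of 8424.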

Results

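RNA sequencing was carried out on unstimulated B cells sorted from the spleens of female C57BL/6J mice. The cells were labelled as wild type or knockout for the histone demethylase LSD1, which the gene Kdm1a encodes. Marginal zone B cells (MZB) are innate-like cells at the edge of the splenic white pulp, and were sorted as B220-positive cells with high CD21 and with CD1d but without CD23. Follicular B cells (FoB) are the recirculating cells of the follicles, and were sorted with CD23, with intermediate CD21 and without CD1d. Cells with CD93, GL7, Thy1.1, F4/80 or CD11b on their surface were excluded from both sorts. The 10 libraries comprised 2 of knockout MZB, 3 of wild-type MZB, 3 of knockout FoB and 2 of wild-type FoB. Expression was given as mRNA molecules per cell for 9690 genes. Whole reads could be worked back from these values, and the libraries held 4161051 to 6711847 of them, with a median of 184 to 319 reads per gene. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

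The sum of mRNA per cell over all genes was 88955.9 ± 12814.6 molecules in wild-type MZB (SD, n = 3) and 50837.4 ± 7920.1 in wild-type FoB (SD, n = 2), a ratio of 1.75. Each of these MZB libraries lay above each of these FoB libraries, with p = 0.1 in a two-sided exact permutation test, the smallest p that 3 and 2 libraries allow, so that tests of this size cannot pass 0.05. Over both genotypes, each of the MZB libraries lay above each of the FoB libraries, with a ratio of 1.98 and an exact two-sided permutation p of 0.00794, again the smallest possible. Knockout MZB held 113330.5 ± 10946.2 molecules per cell (SD, n = 2). The ratio to wild-type MZB was 1.27, and both knockout libraries lay above the wild-type libraries, which held 74815.0, 99800.0 and 92252.8. The exact two-sided permutation p was 0.2, in a test that again could not go below 0.1, so the difference is not shown to exceed the spread between libraries. Knockout FoB held 49138.1 ± 6131.0 (SD, n = 3), a ratio of 0.967 to wild-type FoB (exact two-sided permutation p = 0.7). Because the libraries differ in this way, the median gene was 0.32 higher on the log2 scale in knockout than in wild-type MZB, 0.05 lower in knockout than in wild-type FoB (log2 −0.05), and 0.78 higher in wild-type MZB than in wild-type FoB. Changes are therefore given per cell and, beside that, after the libraries were rescaled to a common level, where a change is relative to the other genes and those medians become 0.04, −0.01 and 0.09.

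Kdm1a (Entrez 99982; chromosome 4, 136550533 to 136602787 on mm10; it overlaps Luzp1) was measured first, because it is the deleted gene. In FoB it stood at 2.11 ± 0.22 mRNA per cell in knockout (SD, n = 3) and 4.96 ± 0.881 in wild-type cells (SD, n = 2), so the knockout level was 42.5% of the wild-type level. In MZB it stood at 5.66 ± 0.401 (SD, n = 2) and 7.54 ± 1.05 (SD, n = 3), or 75% of the wild-type level. Each knockout library lay below each wild-type library of the same cell type. The knockout MZB libraries held 5.38 and 5.94 molecules per cell, and the wild-type ones 6.37, 8.36 and 7.90. The knockout FoB libraries held 2.04, 2.36 and 1.93, and the wild-type ones 5.58 and 4.34. Kdm1a fell by 1.12 on the log2 scale in FoB (limma, Benjamini-Hochberg adjusted p = 4.31e-05). In MZB the per-cell change of −0.39 did not pass (limma adjusted p = 0.118), while the rescaled change of −0.67 did, at 61% of the wild-type level (limma adjusted p = 0.000676; the alternatives ranged from 1.48e-05 to 0.51). The difference of 0.73 between the knockout effects in the 2 cell types did not pass (limma adjusted p = 0.102; the alternatives ranged from 0.0396 to 0.548). It did pass with limma voom (0.43, adjusted p = 0.0396) and without wild-type MZB library 2 (0.81, limma adjusted p = 0.0495). Which exons were deleted is not given in the sources used here, so it is not known whether the reads of Kdm1a lie in the deleted part. It is also not known whether some knockout cells kept the gene.

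**Figure D1:**
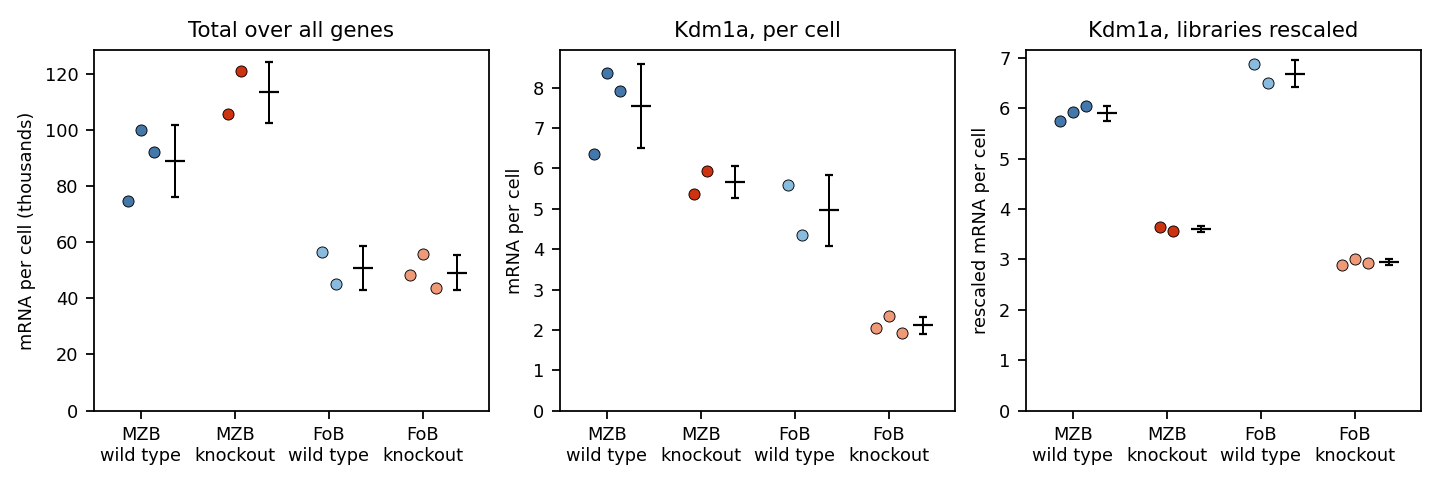
Total mRNA per cell (left), Kdm1a mRNA per cell (middle) and Kdm1a after rescaling (right) in knockout and wild-type MZB and FoB, with points for libraries and error bars for group means ± SD. The knockout MZB libraries hold 105590.4 and 121070.6 molecules in total, and Kdm1a averages 5.66 in knockout and 7.54 in wild-type MZB against 2.11 and 4.96 in FoB per cell.

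Knockout MZB were compared with wild-type MZB to ask which transcripts of these cells depend on LSD1. Genes that are usually high in follicular B cells, immature B cells and B-1 cells, and interferon-stimulated genes, were among those that rose. Itgb7, the integrin β7 chain used in lymphocyte homing, rose from 4.74 ± 0.996 mRNA per cell in wild-type (SD, n = 3) to 17.45 ± 3.45 in knockout MZB (SD, n = 2), against 15.59 ± 1.83 in wild-type FoB (SD, n = 2). After rescaling, Itgb7 in knockout MZB lay below wild-type FoB, at 11.03 ± 1.23 (SD, n = 2) and 21.08 ± 0.448 (SD, n = 2). Fcer2a, which encodes CD23, rose from 13.3 ± 3.85 to 33.71 ± 1.76 although both populations were sorted as CD23-negative, and wild-type FoB held 93.71 ± 18.9. Klf2, a transcription factor of lymphocyte trafficking and quiescence, rose from 4.43 ± 0.902 to 9.01 ± 1.96, with 26.66 ± 4.33 in wild-type FoB.

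Among the genes with the largest rises, Cort, the neuropeptide gene cortistatin, went from 0.113 ± 0.0253 to 3.22 ± 0.681 mRNA per cell, on means of 1.3 and 28 reads. Its neighbour Cenps, a centromere protein gene whose model lies next to that of Cort without overlapping it on chromosome 4, went from 0.484 ± 0.087 to 3.38 ± 0.139. Both lie, as does Znf41-ps, within 15 Mb of Kdm1a, a region in which 11.2% of genes were called after rescaling, against 5.5% elsewhere (two-sided Fisher's exact p = 0.000955). Ly6c2, a surface antigen of monocytes and memory lymphocytes, went from 0.235 ± 0.146 to 4.04 ± 1.51, a log2 change of 3.01 ± 0.21 per cell (SE) and 2.56 ± 0.29 after rescaling. Alox5ap, which encodes the protein that activates 5-lipoxygenase, went from 1.35 ± 0.683 to 5.96 ± 0.033. Ptprv, a receptor phosphatase gene that overlaps Ptpn7, went from 1.59 ± 1.09 to 9.24 ± 0.0994, and reads of the overlap cannot be assigned with certainty. The same holds for Ifit1bl1, an interferon-induced gene that overlaps Ifit1, Ifit3b and Ifit1bl2, which went from 1.024 ± 0.434 to 4.25 ± 0.618. Among the genes that fell, Rgs18, a regulator of G-protein signalling, went from 4.004 ± 0.648 to 1.24 ± 0.0329, Rnpep, an aminopeptidase gene, from 6.71 ± 2.53 to 2.27 ± 0.0853, and Fcamr, the Fc receptor for IgA and IgM, from 12.14 ± 4.09 to 5.33 ± 0.0717. The pseudogene Znf41-ps went from 3.03 ± 0.324 to 1.36 ± 0.175. Each knockout library lay on the same side of each wild-type library for all of these genes, and their calls held after rescaling, but that of Cort was lost when wild-type MZB library 1 was also left out. The other genes with large changes encode small nucleolar RNAs (Snora20, Snord43, Snord72, Snord12 and Snora75). They lie inside longer genes and rest on a few reads, as for Snord43 within Rpl3, with means of 1 read in knockout and 6 in wild-type libraries.

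**Figure D2:**
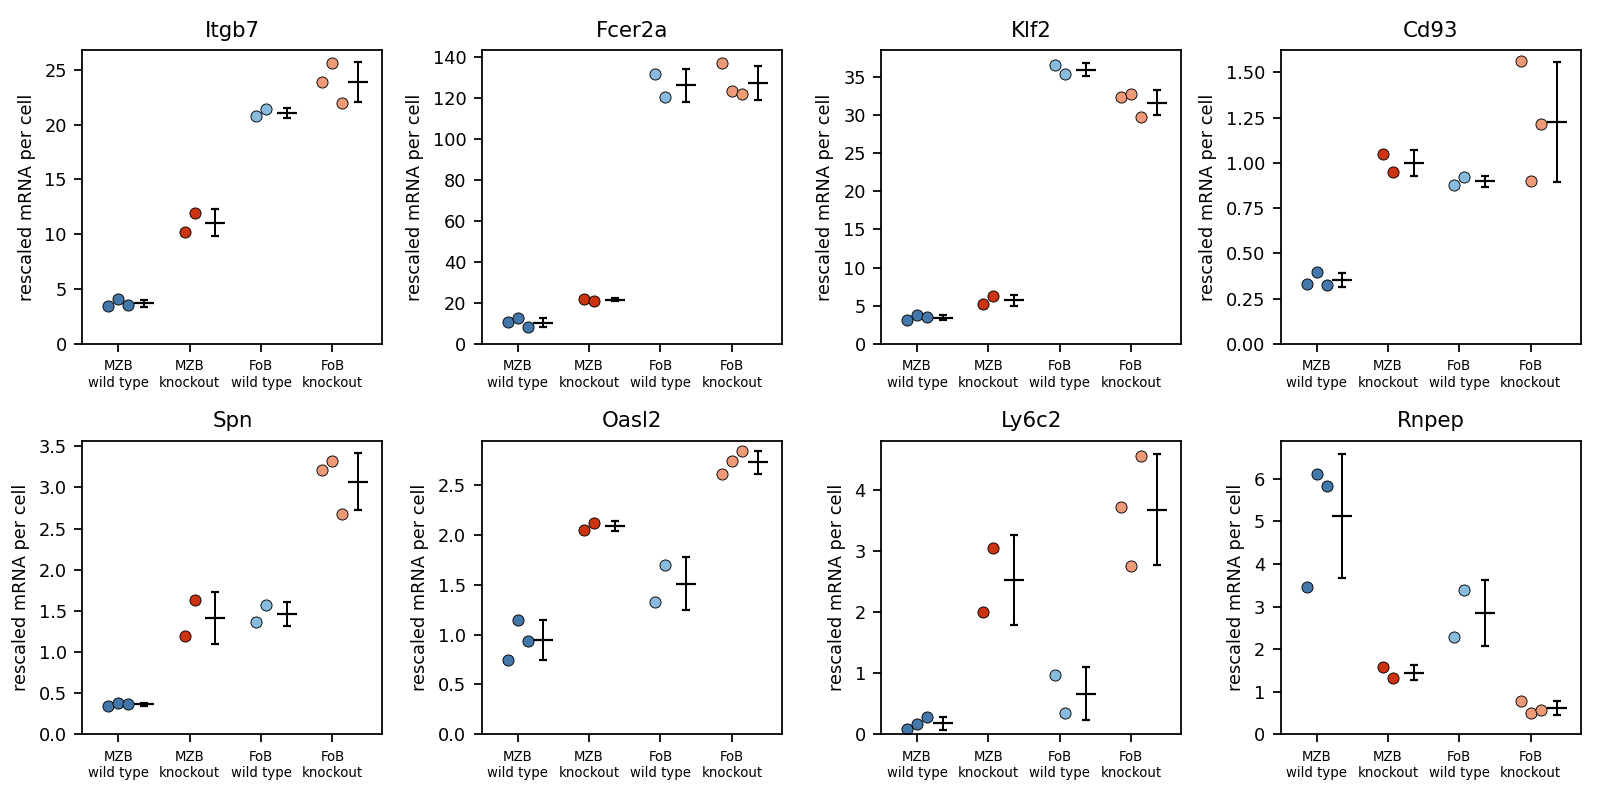
Expression of 8 genes in the 4 groups, as mRNA per cell after rescaling the libraries to a common level, with points for libraries and error bars for group means ± SD. In MZB, Itgb7, Fcer2a, Klf2, Cd93, Spn, Oasl2 and Ly6c2 lie higher in knockout libraries and Rnpep lies lower, with rescaled log2 changes from −1.60 for Rnpep to 2.56 for Ly6c2.

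Of the 12 follicular B cell genes tested, 7 rose per cell and 0 fell in knockout MZB, 8 rose when adjusted over the list alone, and after rescaling 4 rose and 1 fell. The list rose against all other genes (limma camera, Benjamini-Hochberg adjusted p = 0.000298; adjusted p = 0.77 with an estimated correlation). Its strongest members were Itgb7 (log2 1.82 ± 0.20 per cell and 1.51 ± 0.10 rescaled, SE), Fcer2a (1.36 ± 0.22 and 1.05 ± 0.14), Klf2 (0.98 ± 0.20 and 0.68 ± 0.09) and Bach2, a repressor of plasma cell differentiation (0.92 ± 0.19 and 0.62 ± 0.15). Of the 15 marginal zone B cell genes tested, none passed per cell or when adjusted over the list alone, and 3 fell after rescaling, or 9 when adjusted over the list alone. Zc3h12c, which encodes a ribonuclease, had the strongest change of them, with a log2 change of −0.77 ± 0.14 rescaled (SE) and −0.49 ± 0.18 per cell. The list lay 0.30 below the median of all genes (median difference −0.30; limma camera adjusted p = 0.000485; adjusted p = 0.77 with an estimated correlation).

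Immature and transitional B cell genes rose in 4 of 6 cases, also when adjusted over the list alone, and in 2 after rescaling (limma camera adjusted p = 0.000298; adjusted p = 0.376 with an estimated correlation). Cd93, whose product the sort excluded, went from 0.451 ± 0.0974 to 1.57 ± 0.0258 mRNA per cell, and Sox4, a transcription factor of early lymphocyte development, from 0.236 ± 0.0965 to 0.902 ± 0.109. Of 6 B-1 cell genes, 4 rose, 5 when adjusted over the list alone and 3 after rescaling (limma camera adjusted p = 2.06e-05; adjusted p = 0.376 with an estimated correlation). Spn, which encodes CD43, went from 0.466 ± 0.0815 to 2.25 ± 0.686, Cd5, a negative regulator of antigen receptor signalling, from 0.369 ± 0.163 to 1.33 ± 0.0551, and Il5ra, the interleukin 5 receptor chain, from 6.95 ± 0.436 to 11.95 ± 1.08. In these 2 lists, Cd93, Sox4, Vpreb3 and Spn stood lower in wild-type MZB than in wild-type FoB after rescaling (log2 −0.88, −1.20, −1.46 and −1.41). Their rises cannot be told apart from the rise of genes high in FoB. The other members that rose per cell, Myb, Cd5, Zbtb32 and Il5ra, did not stand lower in wild-type MZB (0.25, 0.47, 0.11 and 0.48). Of the 24 interferon-stimulated genes, 18 rose, 23 when adjusted over the list alone and 7 after rescaling, and 0 fell (limma camera adjusted p = 2.2e-10; adjusted p = 0.603 with an estimated correlation). Oasl2, an oligoadenylate synthetase-like antiviral gene, went from 1.22 ± 0.398 to 3.29 ± 0.364, Oas1a, which makes the activator of ribonuclease L, from 2.84 ± 0.552 to 6.50 ± 1.31, and Cmpk2, a mitochondrial nucleotide kinase gene, from 1.49 ± 0.259 to 3.25 ± 0.244.

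Cell cycle genes rose per cell in 18 of 25 cases and in 23 when adjusted over the list alone, but in 1 after rescaling (limma camera adjusted p = 3.45e-05; adjusted p = 0.785 with an estimated correlation). Mki67, the proliferation antigen, stood at 12.52 ± 3.43 mRNA per cell in knockout and 7.57 ± 2.01 in wild-type MZB, a log2 change of 0.71 ± 0.19 per cell (SE) and 0.41 ± 0.15 rescaled, which did not pass. Of 13 immediate early and stress genes, 7 rose, 9 when adjusted over the list alone and 4 after rescaling (limma camera adjusted p = 0.0119; adjusted p = 0.951 with an estimated correlation). Jund, an AP-1 subunit, went from 3.60 ± 0.645 to 7.72 ± 1.31, and Ier2, an early response gene, from 2.50 ± 0.381 to 5.16 ± 0.109. Of 27 adhesion and migration genes, 9 rose, 12 when adjusted over the list alone, and 7 rose and 1 fell after rescaling (limma camera adjusted p = 0.0039; adjusted p = 0.951 with an estimated correlation). Cxcr4, the chemokine receptor for CXCL12, went from 4.40 ± 0.223 to 12.63 ± 3.31, and Itgam, which encodes the CD11b that the sort excluded, from 0.339 ± 0.0663 to 1.58 ± 0.27. Of 34 oxidative phosphorylation genes, 5 rose, 16 when adjusted over the list alone and 1 after rescaling (limma camera adjusted p = 0.0396; adjusted p = 0.951 with an estimated correlation). The member with the smallest p was Sdhb, a subunit of succinate dehydrogenase, which went from 11.31 ± 1.46 to 21.88 ± 1.63.

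Markers of other cell types also moved with the knockout in MZB. Of 4 macrophage and monocyte markers tested, 2 rose, also when adjusted over the list alone, and 1 after rescaling, Ly6c2 (limma camera adjusted p = 0.0052; adjusted p = 0.376 with an estimated correlation). Both dendritic cell markers tested rose, also when adjusted over the list alone and after rescaling. They were Flt3, a cytokine receptor of progenitors and dendritic cells, from 0.350 ± 0.0903 to 2.12 ± 0.289 mRNA per cell, and Cst3, a protease inhibitor, from 11.95 ± 1.58 to 20.87 ± 4.59. The T cell marker Lck went from 4.11 ± 0.387 to 7.74 ± 0.498, the platelet integrin Itgb3 from 0.971 ± 0.095 to 2.25 ± 0.211, and the endothelial marker Pecam1 from 22.26 ± 3.47 to 35.63 ± 2.38. Lck, Itgb3 and Pecam1 were the members of their lists in the table, and genes of neutrophils and erythroid cells were not among those measured. Of 2 NK cell markers, 1 rose, also when adjusted over the list alone, and 0 did after rescaling. Sorted wild-type FoB expressed several of these markers as well. After rescaling, Cst3 stood at 15.17 in wild-type FoB against 9.35 in wild-type MZB, and Lck at 4.10 against 3.24. Itgb3 stood at 2.35 against 0.76 and Pecam1 at 23.32 against 17.4, while Flt3 stood lower in FoB, at 0.125 against 0.271. Whether the rises in knockout MZB came from other cell types was not tested.

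No member of the Notch pathway list, 18 genes, passed per cell, when adjusted over the list alone or after rescaling (limma camera adjusted p = 0.485). Of 15 genes of the LSD1 complex and its partners, 4 rose, among them Gfi1, a repressor that recruits LSD1, from 0.265 ± 0.0603 to 0.858 ± 0.00267 mRNA per cell, and Zfp217, from 5.91 ± 0.918 to 10.89 ± 1.31. Adjusted over the list alone 8 rose, and after rescaling 2 rose and Kdm1a fell (limma camera adjusted p = 0.468). Of 17 canonical NF-kB components and targets, 5 rose, 9 when adjusted over the list alone and 2 after rescaling, and Tnfaip3, an inhibitor of that pathway, went from 3.33 ± 0.549 to 5.49 ± 1.22 (limma camera adjusted p = 0.246). Of 11 non-canonical NF-kB genes, 1 rose, 6 when adjusted over the list alone and 0 after rescaling (limma camera adjusted p = 0.756). Of 22 B cell transcription factors, 3 rose, 6 when adjusted over the list alone, and 3 rose and 1 fell after rescaling (limma camera adjusted p = 0.468). Their examples were Klf2, Bach2 and Id3, an inhibitor of E proteins, which went from 5.75 ± 0.508 to 12.92 ± 1.16. Bcl6, which encodes a transcriptional repressor and is 1 of the 2 germinal centre genes tested, went from 2.75 ± 0.257 to 5.43 ± 0.441. Of 26 B cell receptor signalling genes, 2 rose, 7 when adjusted over the list alone, and 1 rose and 1 fell after rescaling (limma camera adjusted p = 0.467). The lists of plasma cell and secretory genes (2 of 14 rose, 3 adjusted over the list alone), apoptosis (1 of 16, 0 adjusted over the list alone), glycolysis (2 of 15, 3 adjusted over the list alone) and antigen presentation (1 of 19, 0 adjusted over the list alone) were not called.

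Over all genes, limma called 1288 higher and 68 lower per cell in knockout MZB at a Benjamini-Hochberg adjusted p under 0.05. After rescaling it called 369 higher and 183 lower, so that the share of higher calls went from 95% to 66.8%, and 418 genes were called on both scales in the same direction. On the recovered reads, limma voom called 557 higher and 550 lower. The per-cell count of 1356 became 272 without knockout MZB library 2, 484 without wild-type MZB library 1 and 2791 without wild-type MZB library 2. Without the first of these, Klf2, Bach2, Zfp217, Mki67, Cst3, Lck, Pecam1, Tnfaip3 and Snora75 lost their calls, without wild-type MZB library 1 Mki67, Pecam1 and Tnfaip3 did, without knockout MZB library 1 Il5ra and Pecam1, and without wild-type MZB library 3 Pecam1.

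Knockout FoB were compared with wild-type FoB to ask which transcripts depend on LSD1 in the other cell type. Fewer genes passed there, and several of them had also changed in MZB. Ly6c2 rose from 0.514 ± 0.392 mRNA per cell in wild-type (SD, n = 2) to 2.60 ± 0.434 in knockout FoB (SD, n = 3), and Spn rose from 1.08 ± 0.0404 to 2.21 ± 0.419. Fcamr fell from 4.34 ± 0.937 to 0.961 ± 0.155, a log2 change of −1.87 ± 0.20 per cell (SE; limma adjusted p = 3.47e-11) with 3 of 3 knockout libraries below both wild-type libraries. Ahnak, a very large scaffold protein of the cell cortex, fell from 4.97 ± 0.884 to 2.64 ± 0.184.

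The interferon-induced Ifit1bl1 rose in FoB from 1.34 ± 0.0318 to 3.02 ± 0.302 mRNA per cell, with the same uncertainty about overlapping reads. Cyb5a, which encodes cytochrome b5, rose from 3.98 ± 1.01 to 7.86 ± 1.89, and Setbp1, a gene of chromosome 18 whose product binds SET, from 1.57 ± 0.295 to 3.19 ± 0.497. Srp54a, a subunit of the signal recognition particle with the near-identical copy Srp54b, rose from 2.46 ± 0.12 to 4.71 ± 0.847, and reads may be split between the copies. Erdr1 (log2 1.48 ± 0.25 per cell, SE), Ctse (1.31 ± 0.22) and Tgtp1 (0.76 ± 0.20) rose and Ide (−0.76 ± 0.20) fell per cell. Their rescaled changes of 1.53 ± 0.40, 1.37 ± 0.30, 0.83 ± 0.17 and −0.74 ± 0.19 (SE) were about as large but did not pass. Erdr1 stood at 43.91 ± 31.9 in the knockout libraries and Ctse at 5.76 ± 4.35 in the wild-type libraries, so that their spread was close to their level. Flt3 rose from 0.0919 ± 0.00381 to 0.423 ± 0.0773. Some genes named for MZB moved the same way in FoB at lower levels. Alox5ap went from 0.248 ± 0.126 to 1.61 ± 0.325, Rnpep from 2.07 ± 0.284 to 0.440 ± 0.103 and Rgs18 from 0.559 ± 0.108 to 0.111 ± 0.03. Rnpep, Ptprv, Fcamr and Ctse lie on chromosome 1 between 130784706 and 135284423, and whether their changes share a cause was not tested.

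Of 24 interferon-stimulated genes, 1 rose in knockout FoB, 2 when adjusted over the list alone and 3 after rescaling, or 10 when adjusted over the list alone (limma camera adjusted p = 2.1e-17; adjusted p = 0.569 with an estimated correlation). The gene that rose was Isg15, a ubiquitin-like antiviral protein, from 0.222 ± 0.0092 to 0.827 ± 0.15 mRNA per cell, on means of 6 and 21 reads. After rescaling, Oasl2 and Usp18, the protease that removes ISG15, also rose, by 0.75 ± 0.14 and 0.56 ± 0.10 (SE). Cell cycle genes as a list lay below the other genes (limma camera adjusted p = 0.00186; adjusted p = 0.929 with an estimated correlation), while 0 of the 25 passed singly and 1 was lower when adjusted over the list alone. Mki67 stood at 0.166 ± 0.0239 in knockout and 0.427 ± 0.0333 in wild-type FoB, and Top2a, the topoisomerase of dividing cells, at 0.333 ± 0.0167 and 0.588 ± 0.0102. Of 4 macrophage and monocyte markers, Ly6c2 rose, also when adjusted over the list alone and after rescaling (limma camera adjusted p = 2.12e-05; adjusted p = 0.163 with an estimated correlation). Itgam stood at 0.277 ± 0.0466 and 0.0937 ± 0.00876, and rose after rescaling. Per cell, none of the 15 marginal zone or the 12 follicular B cell genes passed in FoB, also when adjusted over the list alone (limma camera adjusted p = 0.564 for both). After rescaling, 1 follicular B cell gene was lower when adjusted over the list alone, and voom also called it lower. It was Cd55, named after its values were seen, with a log2 change of −0.47 ± 0.11 (SE) rescaled and −0.51 ± 0.20 per cell. Apart from Spn among the B-1 cell genes, Flt3 among the dendritic cell markers and Kdm1a itself, the other lists had 0 members past the threshold per cell.

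Over all genes, limma called 40 higher and 29 lower per cell in knockout FoB, and 38 higher and 12 lower after rescaling, with 31 called on both scales in the same direction and a share of higher calls of 58% and 76%. Of the 29 lower calls per cell, 15 were microRNA genes and 4 small nucleolar or Cajal body RNA genes, which rest on a few reads, and without such genes 46 were higher and 14 lower. limma voom called 72 higher and 31 lower. The per-cell count of 69 became 106 without knockout FoB library 3 and 39 without wild-type FoB library 1. Without wild-type FoB library 1, Srp54a, Tgtp1, Ide, Spn and Flt3 lost their calls, without wild-type FoB library 2 Ctse, Cyb5a, Setbp1, Srp54a, Tgtp1, Ahnak, Spn and Flt3 did, without knockout FoB library 2 Cyb5a, Srp54a, Tgtp1 and Ide, and without knockout FoB library 3 Tgtp1 and Ide.

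Wild-type MZB were compared with wild-type FoB as the background against which the knockout was read. The genes that part these cells in textbooks stood far apart. S1pr3, a sphingosine 1-phosphate receptor that holds MZB in the marginal zone, stood at 22.06 ± 3.31 mRNA per cell in MZB (SD, n = 3) and 0.451 ± 0.0981 in FoB (SD, n = 2). The tetraspanin gene Cd9 stood at 19.25 ± 2.61 and 0.541 ± 0.0556, and Dtx1, a target and regulator of Notch signalling, at 58.1 ± 7.04 and 6.98 ± 2.22. Klf2 went the other way, with 4.43 ± 0.902 in MZB and 26.66 ± 4.33 in FoB, as did Fcer2a, the CD23 gene by which the cells were sorted, which is therefore no finding here.

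Of the genes named here, Tsga13 had the highest log2 difference, 5.92 ± 0.18 per cell (SE) and 5.55 ± 0.10 rescaled, on a mean of 0.5 reads in FoB, and S1pr3 came next with 4.89 per cell. Plxnd1, a semaphorin receptor gene, Ackr2, a decoy chemokine receptor gene, Myof, a membrane repair gene, Cd300lf, an inhibitory receptor gene, and AW011738, which overlaps Perm1, stood at 4.64, 4.60, 4.60, 4.39 and 4.32 per cell, and Cd9 at 4.53. Lower in MZB were Pde2a, a cyclic nucleotide phosphodiesterase gene (log2 −2.56 ± 0.19 per cell and −3.24 ± 0.13 rescaled, SE), Myadm (−2.32 and −2.98), the calcium channel gene Cacna1i (−2.19 and −2.88), Ahnak (−2.15 and −2.82), the intermediate filament gene Vim (−2.01 and −2.77) and Rflnb (−2.01 and −2.65). Of the 15 marginal zone B cell genes, 14 were higher and 1 lower in MZB, also when adjusted over the list alone, and 13 and 1 after rescaling (limma camera adjusted p = 8.23e-23; adjusted p = 0.123 with an estimated correlation). Of the 12 follicular B cell genes, 2 were higher and 9 lower, also when adjusted over the list alone, and 0 and 11 after rescaling (limma camera adjusted p = 6.87e-26; adjusted p = 0.123 with an estimated correlation). The sort fixed the direction of Cr2, Cd1d1 and Fcer2a in these lists, which encode CD21, CD1d and CD23. Without them, 12 of 13 marginal zone genes were higher and 1 lower, and 2 of 11 follicular genes were higher and 8 lower, also when adjusted over the list alone (limma camera adjusted p = 1.22e-19 and 1.15e-20; adjusted p = 0.142 for both with an estimated correlation).

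All 25 cell cycle genes were higher in MZB per cell, also when adjusted over the list alone, and 18 after rescaling (limma camera adjusted p = 1.23e-05; adjusted p = 0.934 with an estimated correlation). Mki67 stood at 7.57 ± 2.01 in MZB against 0.427 ± 0.0333 in FoB, and Top2a at 7.15 ± 1.95 against 0.588 ± 0.0102. Of 13 immediate early and stress genes, 3 were higher and 3 lower per cell, also when adjusted over the list alone, while 1 was higher and 10 lower after rescaling (limma camera, direction down, adjusted p = 3.02e-08; adjusted p = 0.561 with an estimated correlation). Among them Jund was lower in MZB by a log2 change of −1.61 ± 0.20 per cell (SE), and Myc, a driver of cell growth, was higher at 19.11 ± 3.38 against 4.95 ± 1.29. The lists of immature B cell genes (3 higher and 2 lower per cell, also when adjusted over the list alone; 1 and 3 rescaled), adhesion genes (15 and 6; 9 and 13 rescaled) and B cell transcription factors (12 and 3; 5 and 13 rescaled) lay below the other genes, with limma camera adjusted p of 0.00508, 0.00387 and 0.00164. With an estimated correlation the adjusted p were 0.561, 0.934 and 0.934. Per cell, the last pair of lists gave the same counts when adjusted over the list alone. Id2, an inhibitor of E proteins, was higher in MZB, at 2.99 ± 0.42 against 0.221 ± 0.0713, and Tcf4, an E protein gene, was too, at 13.62 ± 1.63 against 3.60 ± 0.523.

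Per cell, 8161 of all 9690 genes were higher and 162 lower in MZB, so a high per-cell count alone does not set a list apart. Of 18 Notch pathway genes, 15 were higher and 1 lower in MZB, also when adjusted over the list alone, and 7 and 3 after rescaling (limma camera adjusted p = 0.567). Their examples were Hes1, a transcriptional repressor induced by Notch, at 8.87 ± 1.61 against 2.12 ± 0.238, and Hes5. Of 24 interferon-stimulated genes, 19 were higher and 0 lower, also when adjusted over the list alone, and 13 and 2 after rescaling, with Isg15 at 3.44 ± 0.721 against 0.222 ± 0.0092 (limma camera adjusted p = 0.146). Of 14 plasma cell and secretory genes, 12 were higher and 1 lower, also when adjusted over the list alone, and 8 and 2 after rescaling, with Pdia4, an isomerase of the endoplasmic reticulum, at 162.9 ± 19.6 against 19.38 ± 4.83 (limma camera adjusted p = 0.294). Of 19 antigen presentation genes, 10 were higher and 0 lower, also when adjusted over the list alone, and 4 and 9 after rescaling, with the costimulatory gene Cd86 at 9.57 ± 1.36 against 1.76 ± 0.377 (limma camera adjusted p = 0.134).

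Over all genes, limma called 8161 higher and 162 lower in MZB per cell, and 3039 higher and 1751 lower after rescaling, with 3200 called on both scales in the same direction and a share of higher calls of 98.1% and 63.4%. Rescaling to a common median gave 2243 higher and 2644 lower, and limma voom 2489 and 2557. Per cell, Kdm1a was higher in MZB by 0.58 ± 0.19 (SE), and after rescaling its change was −0.17 ± 0.07, the opposite direction, and did not pass. Without wild-type FoB library 2 the per-cell call of Kdm1a was lost, and without wild-type FoB library 1 that of Ier2, which was lower in MZB.

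The knockout effect in MZB was then tested against that in FoB, to ask which transcripts depend on LSD1 differently in the 2 cell types. The effects differed for the scaffold gene Ahnak and for the follicular B cell genes Itgb7, Fcer2a and Klf2. Ahnak stood at 2.68 ± 0.109 mRNA per cell in knockout MZB (SD, n = 2) and 0.889 ± 0.164 in wild-type MZB (SD, n = 3), but at 2.64 ± 0.184 in knockout FoB (SD, n = 3) and 4.97 ± 0.884 in wild-type FoB (SD, n = 2). Its effects differed by a log2 change of 2.17 ± 0.26 per cell (SE, limma adjusted p = 4.77e-09) and 1.83 ± 0.20 rescaled (SE, limma adjusted p = 0.00917). Itgb7 differed by 1.69 ± 0.28 and 1.33 ± 0.14, with 17.14 ± 2.76 in knockout against 15.59 ± 1.83 in wild-type FoB. Klf2 differed by 1.21 ± 0.28 and 0.86 ± 0.13, with 22.66 ± 2.98 against 26.66 ± 4.33 in FoB.

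Bcl6 (log2 difference 1.16 ± 0.27 per cell, SE), Id3 (1.21 ± 0.28), Jund (1.23 ± 0.28) and Itgb3 (1.26 ± 0.26) also passed on both scales. Fcer2a (1.39 ± 0.31), Bach2 (0.98 ± 0.27), Cd93 (1.06 ± 0.26), Cd5 (1.31 ± 0.27), Gfi1 (0.90 ± 0.26), Mki67 (1.35 ± 0.27), Top2a (1.10 ± 0.27), Itgam (1.01 ± 0.26), Ly6c2 (1.10 ± 0.30) and Flt3 (1.03 ± 0.26) passed per cell and not after rescaling, where they ran from 0.47 ± 0.41 (Ly6c2) to 1.13 ± 0.22 (Mki67). The small nucleolar RNA genes Snora20, Snord45b and Snord89 had higher and Snord98, Snord16a, Snord73a and Snord72 lower effects in MZB per cell. None of them passed after rescaling, with differences that stayed large but had wider errors, as for Snord98 (−2.28 ± 0.46 per cell and −2.89 ± 1.27 rescaled, SE) and Snord45b (2.38 ± 0.49 and 2.19 ± 1.37). Of the 12 follicular B cell genes, 5 had a higher effect in MZB, 7 when adjusted over the list alone and 2 after rescaling, and the list as a whole was called (limma camera adjusted p = 0.000482; adjusted p = 0.957 with an estimated correlation). The same held for cell cycle genes (6 of 25, 20 adjusted over the list alone and 0 rescaled; limma camera adjusted p = 1.12e-07), B-1 cell genes (2 of 6, 5 adjusted over the list alone and 0 rescaled; 0.00213), immature B cell genes (2 of 6, 4 adjusted over the list alone and 0 rescaled; 0.0382) and immediate early genes (1 of 13, 7 adjusted over the list alone and 1 rescaled; 0.042). With an estimated correlation the adjusted p was 0.957 for each of these lists. The marginal zone genes lay lower as a list (limma camera adjusted p = 0.042; adjusted p = 0.957 with an estimated correlation), with 0 of 15 passing singly per cell, also when adjusted over the list alone. Without Cr2, Cd1d1 and Fcer2a in their lists, the calls of the marginal zone and immediate early lists were lost (limma camera adjusted p = 0.082 and 0.0504). Interferon-stimulated genes were not called (0 of 24, 0 adjusted over the list alone; limma camera adjusted p = 0.701).

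**Figure D3:**
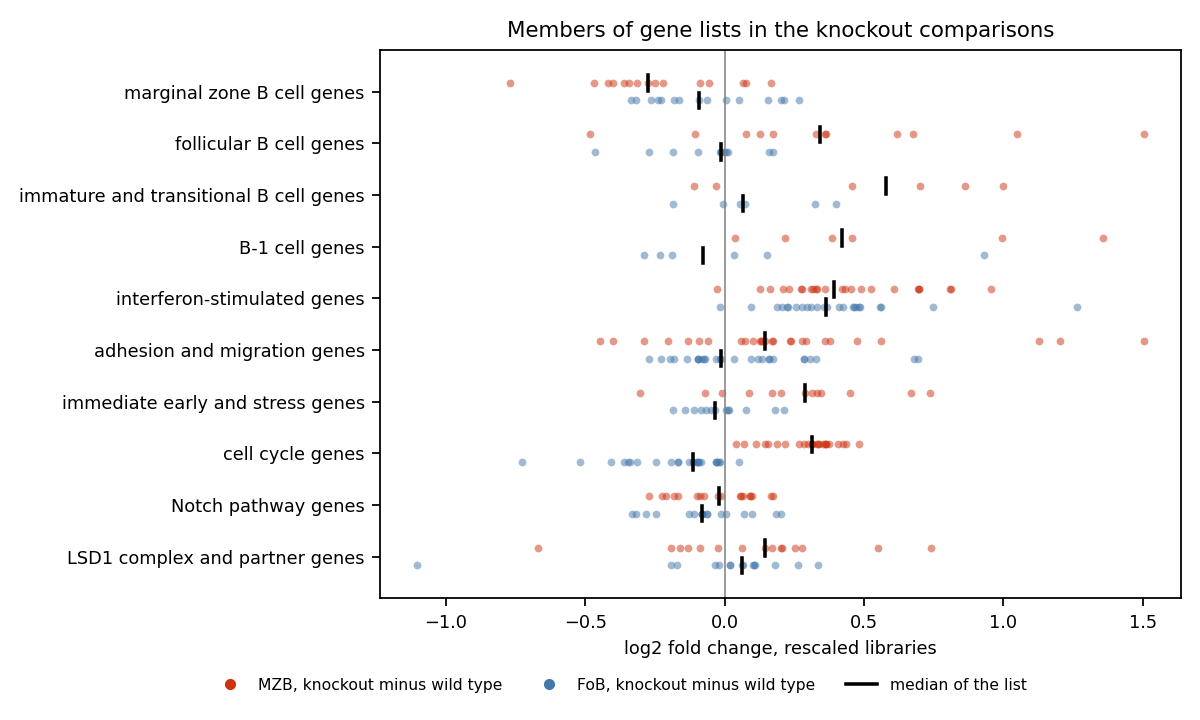
Log2 fold changes of the members of 10 gene lists after rescaling, knockout minus wild type, in MZB (red) and FoB (blue), with black bars for list medians. The median of the follicular B cell genes is 0.34 and that of the marginal zone B cell genes −0.28 in MZB, and that of the interferon-stimulated genes is 0.39 in MZB and 0.36 in FoB.

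Over all genes, limma called 196 higher and 31 lower effects in MZB than in FoB per cell, 16 higher and 11 lower after rescaling, with 20 called on both scales in the same direction, and voom 194 higher and 423 lower, so the share of higher calls ran from 86.3% through 59.3% to 31.4%. The per-cell count of 227 became 91 without knockout MZB library 2, 143 and 744 without wild-type MZB libraries 1 and 2, 637 without knockout FoB library 2 and 59 without wild-type FoB library 1. Klf2, Bcl6, Id3 and Jund lost their calls without knockout MZB library 2 and also without wild-type FoB library 1, while Ahnak, Itgb7 and Itgb3 passed with each library left out in turn. Of the genes that passed per cell alone, Fcer2a, Bach2, Cd93, Cd5, Gfi1, Itgam, Top2a, Ly6c2, Flt3 and Snord98 lost their calls without wild-type FoB library 1, and Bach2, Cd93, Gfi1, Itgam, Mki67, Top2a, Ly6c2, Flt3 and Snord73a without knockout MZB library 2. Bach2, Gfi1, Top2a and Ly6c2 lost them without wild-type MZB library 1, Bach2 without wild-type MZB library 3, Bach2, Gfi1 and Itgam without knockout FoB library 3, Gfi1 without knockout MZB library 1 or knockout FoB library 1, and Gfi1, Itgam, Snord45b, Snord16a and Snord73a without wild-type FoB library 2.

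The calls of the knockout in MZB were last set against the difference between the wild-type cells. After rescaling, 224 genes that rose in knockout MZB were lower in wild-type MZB than in FoB, where independent lists would share 66.7 (two-sided Fisher's exact p = 1.28e-77), and Itgb7, Fcer2a, Klf2, Bach2, Jund and Bcl6 were among them. Of the genes that fell, 170 were higher in wild-type MZB, against 57.4 for independent lists (two-sided Fisher's exact p = 2.3e-70), and Zc3h12c was 1 of them. Per cell these overlaps were 124 (21.5 for independent lists) and 65 (57.3). Across genes, which are not independent replicates, the log2 changes of the 2 comparisons had a Pearson correlation of −0.48 after rescaling and −0.50 per cell. Both comparisons use the wild-type MZB libraries, and in 100 simulations with an unchanged knockout the correlation had a median of −0.09 and ran from −0.13 to −0.04. The covariance was −0.0735 after rescaling against a simulated median of −0.0071. The simulated unchanged knockout gave a median of 0 and at most 2 calls after rescaling, while per cell it gave a median of 18 and, in 3 of 100 draws, as many calls as the 1356 observed. The simulations drew errors separately for each gene, so errors shared by many genes could widen these ranges. Because 3 wild-type MZB libraries cannot be divided into parts of at least 2, part of the excess may come from the shared libraries.

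**Figure D4:**
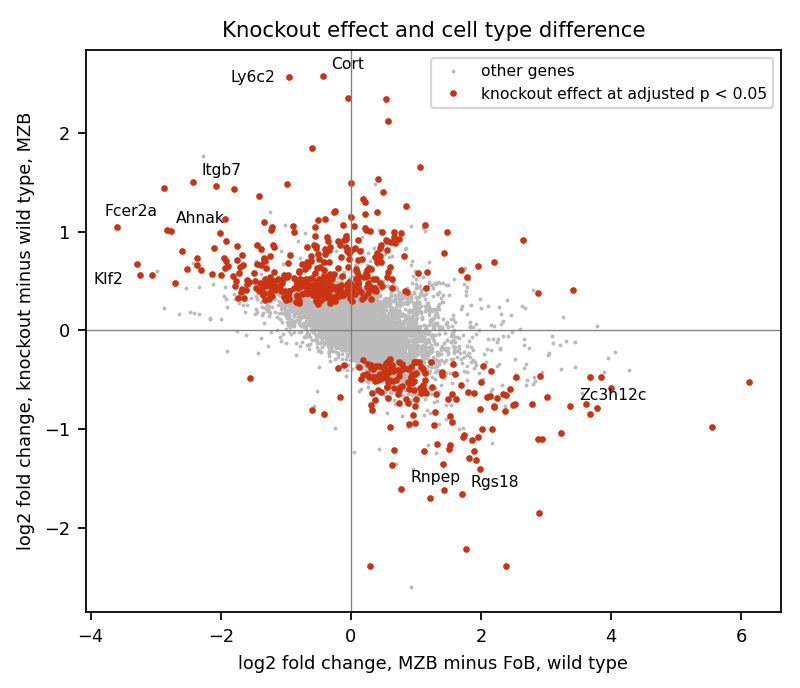
Log2 fold change of each gene after rescaling, knockout minus wild-type MZB (vertical axis) against wild-type MZB minus wild-type FoB (horizontal axis), with knockout calls in red. Genes that rose lie mostly to the left and genes that fell mostly to the right, with Fcer2a at −3.59 and 1.05 and Zc3h12c at 3.37 and −0.77.

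The calls in the 2 cell types were also compared with each other. After rescaling, 29 genes rose in both knockouts, against 1.4 for independent lists, and 8 fell in both, against 0.2 (two-sided Fisher's exact p = 2.79e-34 and 6.45e-12). Ly6c2, Spn, Flt3, Itgam, Ifit1bl1 and Oasl2 rose in both, and Kdm1a and Fcamr fell in both. Across all genes the log2 changes of the 2 knockout comparisons had a Pearson correlation of 0.09, and these comparisons share no libraries.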

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

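Of the tests in this part, the test of the same direction near Kdm1a was written before its result was seen, although the grouping of calls there had been seen, and the other tests on patterns were chosen only after the result was seen. The genes and lists that follow were picked out because the tested knockout effect differed between MZB and FoB per cell. Values are log2 differences between the effects, MZB minus FoB, and 7 of the 31 genes also passed after rescaling (Ahnak, Itgb7, Klf2, Bcl6, Id3, Jund and Itgb3).

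The effect was higher in MZB for Snora20 (2.42), Snord45b (2.38), Ahnak (2.17), Snord89 (1.97), Cort (1.96), Itgb7 (1.69), Vim (1.59), Cenps (1.56), Myadm (1.48), Fcer2a (1.39), Mki67 (1.35), Cd5 (1.31), Itgb3 (1.26), Jund (1.23), Klf2 (1.21), Id3 (1.21) and Bcl6 (1.16). It was also higher for Ly6c2 (1.10), Top2a (1.10), Cd93 (1.06), Flt3 (1.03), Itgam (1.01), Bach2 (0.98), Pde2a (0.96) and Gfi1 (0.90). It was lower in MZB for Snora75 (−1.09), Znf41-ps (−1.11), Snord72 (−1.60), Snord73a (−1.62), Snord16a (−1.74) and Snord98 (−2.28). Among lists, the median difference over that of all genes was −0.21 for marginal zone B cell genes, 0.30 for follicular B cell genes, 0.51 for immature and transitional B cell genes, 0.41 for B-1 cell genes, 0.23 for immediate early and stress genes and 0.41 for cell cycle genes, and no list kept its call with an estimated correlation.

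Total mRNA per cell in knockout MZB was 1.27 times that in wild-type MZB. The tables argue against sequencing depth as the source, since the ratio of mean recovered reads was 0.965, and against a rise of a few genes, since the median gene moved by 0.927 of the log2 change of the total. Random error in the factor per library stays open, because the difference was 2.01 standard errors of the spread within groups, between the bounds of 1 and 3 set for the test. With 2 and 3 libraries, and with the making of the factor not given, it cannot be told apart from a rise of mRNA in the knockout cells.

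Genes high in FoB were higher in knockout MZB, with 44 higher and 1 lower among 74 genes that stood at least 1.5 (log2) lower in wild-type MZB after rescaling. The tables argue against unequal scale, since rescaling removes a factor common to all genes of a library. The median change of these 74 genes was then 0.5, against 0.04 for all genes. Genes picked in the same way had medians of at most 0.06 in 100 simulations with an unchanged knockout. Those simulations held no unequal scale and drew errors separately for each gene, so errors shared by many genes could exceed that range. An admixture at wild-type FoB levels is argued against as the whole source. The best common share, computed with rescaled wild-type FoB levels, was 13.6%, and 28.4% of these genes deviated from it. On rescaled values this is a share of mRNA, and the share of cells would be larger, since FoB held less mRNA per cell. The test used the error of the knockout effect alone and left out that of the FoB libraries, so 28.4% may be too high. Single genes needed shares from 5.6% (Pde2a), 6.9% (Klf2) and 9.6% (Fcer2a) to 17.9% (Vim) and 42.2% (Itgb7). Those of Bach2 (11.1%), Bcl6 (13.2%) and Ahnak (16.5%) lay near the common share. FoB in a knockout sort may carry the knockout too, and shares with knockout FoB levels were not computed. After rescaling, Ahnak stood lower in knockout than in wild-type FoB (3.696 against 6.86), so its share would then be larger. Itgb7 stood at 23.84 against 21.08, Klf2 at 31.58 against 35.95, Fcer2a at 127.2 against 126 and Pde2a at 8.935 against 9.355. Bach2 stood at 10.59 against 10.64, Bcl6 at 10.25 against 11.9 and Vim at 26.85 against 31.44. The shares of these single genes would thus stay unequal. The 74 genes were not tested against knockout FoB levels, so whether knockout FoB were the whole source cannot be decided. The sort excluded CD23-positive cells. The 102 genes high in MZB had a median of −0.38 where the common share gives −0.21, and 82 of them lay below 0. An admixture of knockout FoB and a smaller admixture of FoB stay open. A loss of LSD1 that moves MZB expression toward that of FoB also stays open, as a hypothesis found and tested on the same data.

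Knockout calls shared by both cell types lay close together, with 13 of 36 within 1 Mb of another after rescaling (permuted median 2, one-sided permutation p = 2e-04) and 14 of 38 per cell (p = 1e-04, the smallest that 10000 permutations can give), as did the FoB calls (p = 0.004 and 8e-04), while the MZB calls after rescaling, 306 of 534 against a permuted median of 293, did not pass (p = 0.18). Those p-values argue against chance placement of the shared calls, and reads shared by overlapping genes are argued against because 0% of the close calls overlapped another, although Srp54a and Srp54b are near copies and Ly6a and Ly6c2 belong to 1 family, and DNA carried along with Kdm1a on chromosome 4 is argued against for these calls because 0 of the 13 lie within 15 Mb of it, all being on chromosomes 3, 5, 7, 12 and 15. Of the MZB knockout calls within 15 Mb of Kdm1a, where 11.2% of genes were called against 5.5% elsewhere (two-sided Fisher's exact p = 0.000955), 64% had the same sign in FoB and 59.9% did elsewhere, and their median log2 change was 0.80 in MZB and 0.18 in FoB (quartiles −0.10 and 0.36), taken in the MZB direction. FoB calls there made up 0.4% of 223 genes against 0.5% elsewhere after rescaling and 0.9% against 0.5% per cell, and these 1 and 2 calls are too few to test whether FoB share the excess. The bound of 65% written against DNA of another strain was met, but the exact 95% interval from 42.5% to 82% passes the 80% that it would need, a condition applied after the value was seen, so for these 25 genes, which include Cort, Cenps and Znf41-ps, carried DNA and regional control by LSD1 cannot be told apart, since they are too few.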

How the results depend on the processing

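The fits on recovered reads with voom, those on rescaled values without 1 library, the one without small RNA genes, the lists with an estimated correlation on rescaled values and the lists without the genes of the sort markers were chosen only after the result was seen. For knockout against wild-type MZB, the 1356 calls became 690 and 2916 with a pseudocount 10 times smaller and larger, 828 with a floor 10 times higher, 552 and 531 with libraries rescaled by log-ratios and by medians, 821 with library weights, 172 at a log2 change of at least 1, 208 when rescaled without wild-type MZB library 1, and 272 to 2791 with 1 library left out. For FoB, the 69 calls became 27 with the larger pseudocount, 128 with the 2 compared groups alone, 41 at a log2 change of at least 1, and 39 to 106 with 1 library left out. For the wild-type cells, the 8323 calls became 4790 and 4887 when rescaled, 5046 with voom, 2930 at a log2 change of at least 1, 4092 when rescaled without wild-type MZB library 1, and 6200 to 8719 with 1 library left out. For the difference between the knockout effects, the 227 calls became 80 and 583 with the pseudocounts, 121 with the floor, 27 and 23 when rescaled, 617 with voom, 143 at a log2 change of at least 1, 2 when rescaled without wild-type MZB library 1, 48 when rescaled without knockout FoB library 3, 389 without small RNA genes, and 59 to 744 with 1 library left out. The 26 list calls became 0 with an estimated correlation, also on rescaled values, 24 without Cr2, Cd1d1 and Fcer2a, and 21 to 26 with 1 library left out, and the 189 genes with opposite directions in the MZB knockout and cell type comparisons became 394 when rescaled. A fold threshold and a higher floor lower counts by construction, and for the other settings the cause was not tested. No filter on low values changed nothing, because the floor removed 0 genes. Where leaving out a library left 1 in a group, that library was assumed to vary like the other groups. Kdm1a reversed between the wild-type cells, from 0.58 to −0.17 and −0.29 when rescaled by log-ratios and medians, −0.28 with voom and −0.15 when rescaled without wild-type MZB library 1, where its cause was not tested. Over all settings, the 2708 values of single named genes kept direction and call in 2402 cases, lost the call in 275, gained it in 27 and reversed in 4. Same-numbered libraries had r from −0.12 to 0.19 over 8 pairs, negative only for library 2 of wild-type MZB and wild-type FoB. In groups of 2 the deviations mirror each other, so these values are not independent and cannot decide whether the numbers mark a pairing. The main fits took no pairing, and a replicate block gave 1042, 116, 5999 and 190 calls in the 4 comparisons and 22 list calls. The planned tests with count models were not run, and limma voom on the recovered reads took their place. Depth limits small RNA genes most, with a median of 3 reads per library for microRNA genes and 6 for small nucleolar RNA genes against 268 for other genes.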

Other observations

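The tests on the zinc finger family and on shared effects were chosen only after the result was seen. Of 264 genes of the Zfp family, most of which encode zinc finger repressors, 18 fell and 6 rose in knockout MZB after rescaling (median log2 change −0.06), whereas per cell the direction turned, with 9 that fell and 24 that rose (median 0.20). The 18 stand against 183 lower calls among all genes after rescaling (two-sided Fisher's exact p = 2.38e-06), and voom called 50 of the family lower and 12 higher. In knockout FoB, limma called 0 of them after rescaling, with 42 at an unadjusted p under 0.05, and voom called 2 higher. Of those that fell in MZB after rescaling, Zfp942, Zfp943, Zfp994, Zfp944 and Zfp946 lie on chromosome 17 between 21926960 and 22456689, and Zfp992, Zfp982 and Zfp984 lie on chromosome 4 between 146449030 and 147812229, within 15 Mb of Kdm1a. Neighbours of this family are similar in sequence, so that their reads may be split between them. A fall of the family as a class is a hypothesis that stays open, because camera with an estimated correlation gave p = 0.105.

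Of 104 microRNA genes, 38.5% were called per cell in the MZB knockout comparison and 17.3% in FoB, and of 69 small nucleolar or Cajal body RNA genes 36.2% and 8.7%, against 13.6% and 0.5% of 9517 other genes. After rescaling, limma called 10 of the microRNA genes, 5 of the small nucleolar or Cajal body RNA genes and 537 of the others in the MZB comparison, while voom called 5, 5 and 1097, a lower share of the small RNA genes than of the others. In FoB limma then called 0, 0 and 50, with 20, 7 and 1353 at an unadjusted p under 0.05, and voom called 0, 0 and 103. The values of the small RNA genes rest on a median of 3 and 6 reads per library, and mature RNAs of these classes carry no poly(A) tail, by which the libraries were selected.

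A shared effect of LSD1 loss in both cell types is a hypothesis for the 29 genes that rose in both after rescaling. Fisher's exact test gave a two-sided p of 2.79e-34, and the 2 comparisons use separate libraries, though perhaps not separate animals. The overlap cannot tell LSD1 loss from any other difference between the genotypes that both cell types carry. Among the genes named here, the 29 included Ly6c2, Spn, Itgam, Flt3, Alox5ap, Srp54a and the interferon-stimulated genes Ifit1bl1, Oasl2 and Usp18. Ly6c2 is on the list of macrophage and monocyte markers and Flt3 on that of dendritic cells, and the other 3 of the 4 macrophage and monocyte markers did not pass after rescaling in either cell type. Cst3, the other dendritic cell marker tested, rose after rescaling in MZB and did not pass in FoB. Both sorts excluded cells with CD11b, F4/80 or Thy1.1.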
